A study of Mus musculus with 2 samples.

How the data were processed

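Expression was measured on 2 Affymetrix mouse arrays hybridised with biotin-labelled RNA from RAW264.7 cells stably expressing LXRα, 1 treated with DMSO and 1 with GW3965 and LG268. Total RNA was isolated with a column kit, per the labels' protocols. The deposited values are intensities, 1 per probe set, on a linear scale. They were made with MAS5, per the submitters' processing notes, and the version is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The deposited intensities had a 2% trimmed mean of 2500 on both arrays, so they were used as deposited without further normalization. MAS5 detection calls were not used here. MAS5 signals near background are noisy and their ratios can be large by chance, which is why a floor was set. Because the arrays were scaled to the same trimmed mean, a ratio is relative to the bulk of the array and a change in total RNA per cell would not be seen.

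Probe sets were named through the platform annotation supplied with the table. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. Symbols of 34741 probe sets were updated by their gene identifier to the GRCm38.p6 annotation and 204 kept the platform's symbol. Probe sets with several or no symbols were not used for genes. No genome coordinates are given because the files name no build. A gene was represented by its probe set of highest mean log2 signal. Probe sets whose names end in _s_at or _x_at can detect several transcripts, and members of near-identical families may share signal.

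Signals below a floor were set to the floor, which was the median (the 50th percentile) of all gene probe sets over both arrays, 276.4. Log2 ratios of the ligand array over the DMSO array were taken from the floored signals. A gene was counted as measured if its brighter signal was above the floor, and as higher or lower at a ratio of at least 2-fold. A gene at the floor on 1 array has a lower bound, written as at least N-fold. With 1 array per group no p-value, standard error or adjusted p was computed, and statements of higher and lower describe these 2 arrays. 22 gene lists were fixed before the data were examined, as were the design, the rule for named genes and the alternatives. The median log2 ratio of each list's measured members was set against the medians of 10000 random lists of the same size, drawn from the measured genes and matched in 20 bins of mean log2 signal. The percentile describes the list within these arrays and is not a test across cultures. No median was computed for a list with fewer than 3 measured members. List members without a probe set of 1 gene symbol were not analysed here.

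Named genes were chosen by this rule. Nr1h3, Nr1h2, Rxra, Rxrb, Abca1, Abcg1, Srebf1, Apoe and Mylip were named whatever their values. The 15 largest and 10 smallest ratios were named among genes above the floor on both arrays, at least 2-fold apart and with all such probe sets in 1 direction, passing over RIKEN clones and predicted genes. Up to 3 members of each list with the largest ratios of at least 1.5-fold were named, and up to 5 genes with the largest bounds in each direction. This gave 75 genes, 74 of them measured. Other list members are quoted with their values and were chosen after these were seen.

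The error of a probe set was estimated from the difference between the 2 brightest probe sets of a gene, as the SD of that difference divided by the square root of 2. The procedure was tested on simulated data built from the 2 arrays, with 200 genes changed, 11138 genes measured and the spread of unchanged probe sets taken from the median absolute deviation in bins of signal. It called 86 of 100 genes changed 3-fold and 93 of 100 changed 6-fold as at least 2-fold apart in the right direction, and none in the wrong one. Of 1000 random lists of unchanged genes, 4.80% fell outside the central 95%. The noise of each probe set was drawn independently, so this checks only the ranking procedure. It does not show how far a list of genes that vary together could move between cultures. The unchanged genes of the same simulation gave the simulated numbers that stand beside the counts of genes. The simulated noise was normal, so these numbers are low estimates if real noise has heavier tails. Its spread came from the observed ratios between the same 2 arrays. It therefore also holds any widespread real difference between them, which would make the numbers high estimates of noise.

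Alternatives were a floor at the 25th or 75th percentile, log2(signal + 32) with no floor, quantile normalization, centring on the median ratio, rescaling to 1 trimmed mean, the mean over probe sets of a gene, leaving out _s_at and _x_at probe sets, only genes above the floor on both arrays, thresholds of 1.5-fold and 3-fold, and other matching of the random lists. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, with matplotlib 3.10.9 for the figures.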

Results

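The series measured gene expression in RAW264.7 cells, a mouse macrophage-like cell line, that stably expressed the liver X receptor LXRα (gene Nr1h3). LXRα is a nuclear receptor for oxidised sterols and acts as a partner of the retinoid X receptors. Cells were cultured for 24 h with the solvent DMSO or with 2 ligands together, the synthetic LXR agonist GW3965 at 1 µM and the RXR agonist LG268 at 100 nM. Each condition had 1 Affymetrix mouse array, so there were no replicates, no test of the difference was possible, and every fold below compares these 2 arrays. Because GW3965 and LG268 were given together, the design holds no measurement of either ligand alone.

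Both arrays held 45101 probe sets with a trimmed mean MAS5 signal of 2500, a median of 282.5 for DMSO and a median of 272.1 for the ligands. A signal floor of 276.4 was set at the median of all gene probe sets, and 50.3% of gene probe sets on the DMSO array and 49.7% on the ligand array lay above it. The absent spike-in Trpn reached at most 137.5 with DMSO and 115.5 with the ligands. Signal ratios of the 3′ to the 5′ control probe sets were 1.18 and 1.15 for Actb and 0.853 and 0.826 for Gapdh and 3.18 and 2.70 for Tfrc, with DMSO and with the ligands. The 3 probe sets for 18S rRNA had a median log2 ratio of 0.50 (ligands over DMSO), the 18 hybridisation spike-in probe sets 0.27 and the 24 poly-A spike-in probe sets 0.03. The number of arrays limited the precision. The only error that could be estimated was the disagreement of probe sets for the same gene. Over 4866 genes with 2 probe sets above the floor on both arrays, the SD of a probe set's log2 ratio was 0.28, which covers measurement within these arrays and not variation between cultures.

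The comparison of ligands with DMSO asks which genes respond to LXR and RXR activation in macrophages. The ligand array showed much higher signals for genes of cholesterol export and lipoproteins. Abca1, the transporter that loads cellular cholesterol onto apolipoproteins, was 27.2-fold higher (signal 2989 with DMSO and 81159 with the ligands), and its 3 probe sets had log2 ratios of 4.76 to 5.52. Apoe, the apolipoprotein secreted by macrophages, was 29.0-fold higher (299 and 8672). The largest ratio measured on both arrays belonged to Cd5l, a secreted scavenger receptor cysteine-rich protein of macrophages that inhibits apoptosis, which was 94.9-fold higher (382 and 36249.9). The lowest ratio measured on both arrays was that of Cadps, 4.18-fold lower, and Klf4, Acp5 and Cx3cr1 were among the next.

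Of 18193 genes, 11077 had a signal above the floor on at least 1 array. Of these, 185 were at least 2-fold higher with the ligands and 86 at least 2-fold lower, 2.45% of the measured genes together, and 88.9% lay within 1.5-fold. At 4-fold, with bounds included, the counts were 28 higher and 4 lower, and at 8-fold 10 higher and 1 lower. The median log2 ratio of the measured genes was -0.03. For comparison, among 10943 unchanged genes of simulated arrays with the spread of the bulk of the real probe sets, 92 were at least 2-fold higher and 88 at least 2-fold lower. At 4-fold the simulation gave 4 higher and 5 lower. The numbers of lower genes, 86 at 2-fold and 4 at 4-fold, did not exceed those of the simulation, while at 3-fold it was 14 against 9. Among genes whose brighter signal exceeded 2178, 99 were at least 2-fold higher and 21 lower, against 4 and 4 in the simulation. Of the 64 genes at least 2-fold apart with a second probe set above the floor, 56 had the same direction in the second probe set and 37 were at least 2-fold apart in it as well.

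**Figure D1:**
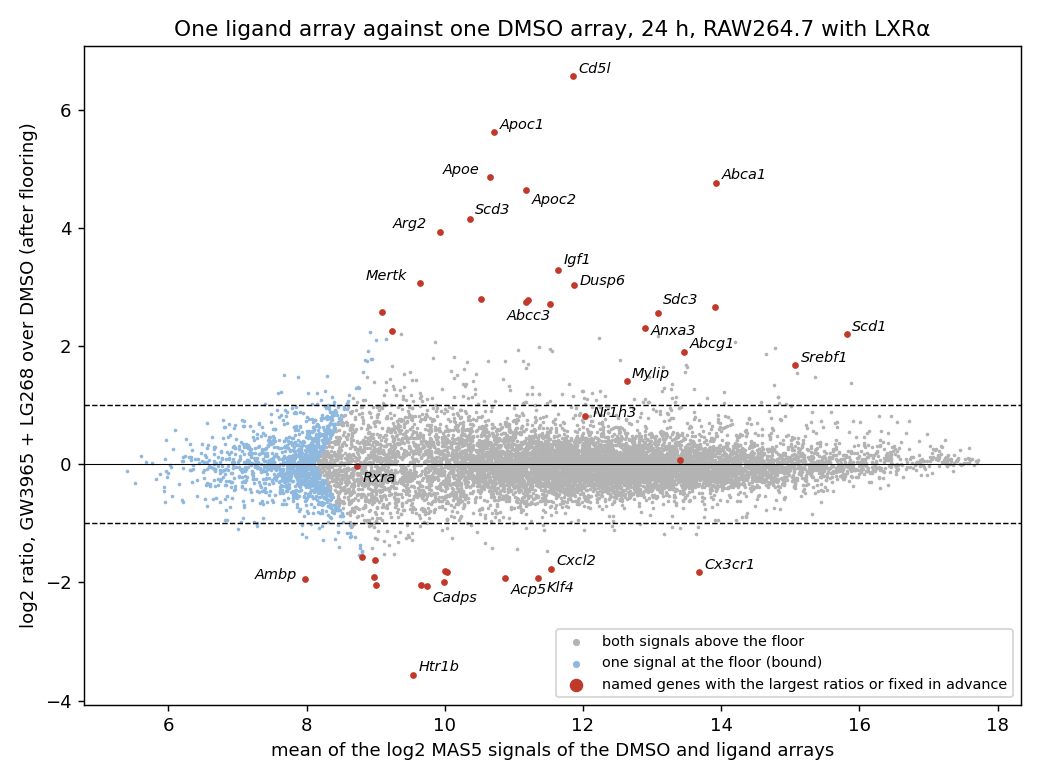
Log2 ratio of the ligand array over the DMSO array (y axis, after flooring) against the mean log2 MAS5 signal of both arrays (x axis) for the 11077 measured genes, with grey points for genes above the floor on both arrays, blue points for genes at the floor on 1 array, red points for named genes and dashed lines at 2-fold. Cd5l, Apoc1, Apoe, Abca1 and Apoc2 stand highest, and the spread of the grey points widens towards low signals.

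The ectopically expressed receptor itself, Nr1h3, had a signal of 3150 with DMSO and 5577 with the ligands, a 1.77-fold higher value from its single probe set. That is a log2 ratio of 0.82, against the probe set SD of 0.28. Whether that probe set detects the introduced transcript, the endogenous one or both is not given in the sources used here. Among its partners, Rxrb was 1.05-fold higher (10594 and 11169), and Rxra was 1.02-fold lower at a low signal (430.3 and 421.4). Another probe set of Rxra above the floor was at 0.33 on the log2 scale. Nr1h2, which encodes LXRβ, was not analysed here. Over the list of nuclear receptors and coregulators, 20 members were measured and none was at least 2-fold higher or lower. The largest differences besides Nr1h3 were the retinoic acid receptors, with Rara 1.77-fold higher and Rarb 1.65-fold lower. The median log2 ratio of the list was 0.06, at the 83.4th percentile of 10000 random lists matched on signal, and 99.1 with the higher floor.

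Genes of cholesterol efflux and lipoprotein handling were the group furthest from the rest. All 11 measured members were higher with the ligands by the brightest probe set of each, and 7 were at least 2-fold higher. Scarb1, at 0.22, had another probe set at -0.25 on the log2 scale. Their median log2 ratio was 1.91, above all 10000 random lists of the same size and signal level. Besides Abca1 and Apoe, the group included Abcg1, which exports cholesterol to lipoprotein particles (3.75-fold higher, 5844 and 21913), and Mylip, a ubiquitin ligase (2.65-fold higher, 3898 and 10342). Apoc1 was at the floor with DMSO (207) and at least 49.2-fold higher with the ligands (13584), and Apoc2 was 25.1-fold higher (462 and 11575). Npc1, the lysosomal cholesterol transporter, had a log2 ratio of 0.21, the smallest of the group. The median was 0.86 without a floor, because the weakly detected members then counted too, and still above all random lists.

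Other genes known as LXR-responsive in macrophages also had high ratios, with 5 of 11 measured members at least 2-fold higher and none at least 2-fold lower. Members had a median log2 ratio of 0.82, above all random lists. This list shares Nr1h3, Mertk, Tgm2, Cd5l, Vegfa, Abca7 and Ccr7 with other lists. After Cd5l, the largest were Arg2, the mitochondrial arginase (at least 15.3-fold higher, 225.5 and 4219), and Mertk, a receptor tyrosine kinase for the uptake of apoptotic cells (at least 8.37-fold higher, 273 and 2313). Both were at the floor with DMSO. Tlr4 and Abca7 had log2 ratios of -0.07 and -0.15, and Lbp, below the floor with the ligands, was at least 1.22-fold lower.

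Fatty acid synthesis genes were higher as a group. Of 21 measured members, 6 were at least 2-fold higher, 10 were at least 1.5-fold higher and none was 1.5-fold lower. Their median log2 ratio was 0.57, above all random lists. Srebf1, which encodes the transcription factor SREBP-1, was 3.19-fold higher (19262 and 61505). The stearoyl-CoA desaturase Scd1 was 4.61-fold higher (26950.0 and 124111), and Lpcat3, which places polyunsaturated chains in phospholipids, was 3.66-fold higher (13481 and 49279). Fasn, the fatty acid synthase, had a log2 ratio of 1.54, and Acaca, which makes malonyl-CoA, one of 1.36. Dgat2 was the lowest member at -0.41.

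Sterol synthesis and uptake genes did not share that direction. Of 20 measured members, 2 were at least 2-fold higher, none was 2-fold lower, and 11 had positive and 9 negative ratios. Their median log2 ratio was 0.09, at the 97.2nd percentile of random lists. It was 0.02, at the 66.6th percentile, when the probe sets of a gene were averaged. The 4 members at least 1.5-fold higher were Tm7sf2, a sterol reductase (2.57-fold), Insig1, which retains SREBP precursors in the endoplasmic reticulum (2.24-fold), Pmvk, phosphomevalonate kinase (1.73-fold), and Mvd, mevalonate diphosphate decarboxylase (1.62-fold). Fdft1, squalene synthase, had the lowest log2 ratio, -0.62. 5 further members of the list were not analysed here.

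PPAR- and retinoid-responsive genes had a median log2 ratio of 0.39, above all random lists, with 5 of 15 measured members at least 2-fold higher and none 2-fold lower. The median was 0.23, at the 99.55th percentile, without a floor. Tgm2, tissue transglutaminase, was 6.99-fold higher (558 and 3897), with log2 ratios from 0.94 to 2.81 over 5 probe sets. The retinoic acid hydroxylase Cyp26b1 was at least 4.71-fold higher, from the floor with DMSO, and the retinaldehyde reductase Dhrs3 was 3.36-fold higher (861 and 2892). Plin2, which coats lipid droplets, had a log2 ratio of 1.47. The members did not all follow, since Rarb and the fatty acid oxidation enzyme Acadvl had log2 ratios of -0.72 and -0.39.

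Genes for the recognition and engulfment of apoptotic cells were split. Of 16 measured members, 4 were at least 2-fold higher and none 2-fold lower, while the median log2 ratio was 0.09, at the 91.0th percentile of random lists. The direction of the median was not fixed, since it was -0.025, between the 47.1st and 50.9th percentiles, with the lower floor, the higher floor and no floor. Besides Mertk, the higher members included its ligand Gas6 (2.51-fold, 385 and 967) and the scavenger receptor Cd36 (2.53-fold, 17499 and 44247, with log2 ratios of 0.28 to 1.75 over 3 probe sets). Anxa1 and Mfge8 had log2 ratios of -0.76 and -0.75. Among 22 measured apoptosis regulators, Cd5l was the only member at least 2-fold apart, and the median log2 ratio was -0.01. Bcl2 was 1.87-fold lower, but its 3 probe sets ranged from -0.91 to 0.07, and Gadd45a was 1.68-fold lower.

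Inflammatory genes diverged. Of 21 measured members, 3 were at least 2-fold higher and 2 at least 2-fold lower, and the median log2 ratio of -0.12 lay at the 9.32nd percentile of random lists. The mean had the other sign, 0.05. The chemokine Ccl2 was 3.87-fold higher (1500.4 and 5800), and Acod1, the itaconate-producing enzyme, was 3.77-fold higher (1551 and 5846). The neutrophil chemokine Cxcl2 was 3.40-fold lower (5501 and 1616), and Tnf had a log2 ratio of -1.04. Nos2, Il6 and Il12b were at the floor on both arrays, so no fold could be given for them. Of 19 measured interferon-stimulated genes, none was at least 2-fold higher or lower. Their median log2 ratio was 0.04, at the 75.6th percentile, and the guanosine triphosphatase Ifi47 had the largest difference, 1.66-fold lower.

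Markers of osteoclasts, a fate RAW264.7 cells can take, were lower in part. Of 12 measured members, 4 were at least 2-fold lower and none 2-fold higher. Their median log2 ratio was -0.33, at the 0.15th percentile of random lists. Acp5, tartrate-resistant acid phosphatase, was 3.78-fold lower (3652 and 966), Ctsk, cathepsin K, was 2.16-fold lower (4083 and 1889), and Ocstamp was 2.09-fold lower at low signals (731 and 349). Nfatc1, the osteoclast transcription factor, had a log2 ratio of -1.01, but its 4 probe sets above the floor ranged from -1.01 to 0.37. Mmp9 and Car2 went the other way, at 0.66 and 0.41. With the higher floor the median was -0.10, at the 15th percentile.

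Macrophage identity markers had a median log2 ratio of 0.05 (86.5th percentile), with 2 of 17 measured members at least 2-fold higher and 1 lower. The exception was the fractalkine receptor Cx3cr1, 3.56-fold lower (24773 and 6961), with its second probe set at -1.39. The β-glucan receptor Clec7a was 2.14-fold higher and the pore-forming protein Mpeg1 2.03-fold higher. Csf1r, Cd14 and Spi1 had log2 ratios of 0.06, -0.01 and -0.08. Of the dendritic cell markers, 5 of 13 were measured, and the costimulatory gene Cd86 was at least 2.19-fold higher, Cd83 1.55-fold higher and Zbtb46 at least 1.54-fold higher. Their median of 0.62 (99.75th percentile) rested on members at the floor with DMSO and was -0.09 without them. Markers of other lineages lay mostly below the floor. 1 of 9 lymphoid, 3 of 10 granulocyte and 3 of 12 fibroblast markers on the array were measured, and none was at least 2-fold apart. The granulocyte and fibroblast medians were 0.13 (76.0th percentile) and -0.51 (6.33rd percentile), and the fibroblast marker Fbln1 was at least 1.65-fold lower.

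Lysosomal genes were modestly higher together. Of 23 measured members, 19 had positive ratios, and the median log2 ratio of 0.31 lay above all random lists. Only Ctsd, cathepsin D, was at least 2-fold higher (2.59-fold, 37315 and 96626), and the proton pump subunit Atp6v0d2 had a log2 ratio of -0.59. Antioxidant and iron genes had a median of 0.11 (95.8th percentile). The metal transporter Slc11a1 was 2.77-fold higher (4781 and 13246), the iron exporter Slc40a1 1.99-fold higher, and the cystine transporter Slc7a11 1.83-fold lower. Glycolytic and hypoxia-responsive genes had a median of 0.08 (93.6th percentile), and only Vegfa, the angiogenic growth factor, was at least 2-fold higher (2.35-fold). The last 2 medians were 0.21 (99.7th percentile) and 0.16 (99.6th percentile) when the probe sets of a gene were averaged.

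Cell cycle genes were slightly lower across the list. Of 29 measured members, 28 had negative ratios by the brightest probe set of each, although none was 1.5-fold apart. Another probe set of Cdc20 was at 0.14. At -0.26, the median log2 ratio lay below all 10000 random lists. Mki67, the proliferation antigen, had a log2 ratio of -0.27, the replicative helicase subunits Mcm3 and Mcm6 had -0.53 and -0.48, and Ccnd1, cyclin D1, had -0.56. Genes of the unfolded protein and integrated stress response had a median of -0.10 (6.80th percentile), or -0.16 (1.64th percentile) after quantile normalization. Within this list, Trib3, Chac1 and Asns, known targets of the transcription factor ATF4, had log2 ratios of -0.73, -0.70 and -0.64, but Atf3 and Ppp1r15a, also known ATF4 targets, had 0.35 and 0.09. The chaperone Pdia4 was 1.78-fold higher. Reference genes had a median of 0.04 (66.2nd percentile). Ywhaz was the only one beyond 1.5-fold, at 1.64-fold higher, and its 7 probe sets ranged from -1.14 to 0.80.

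**Figure D2:**
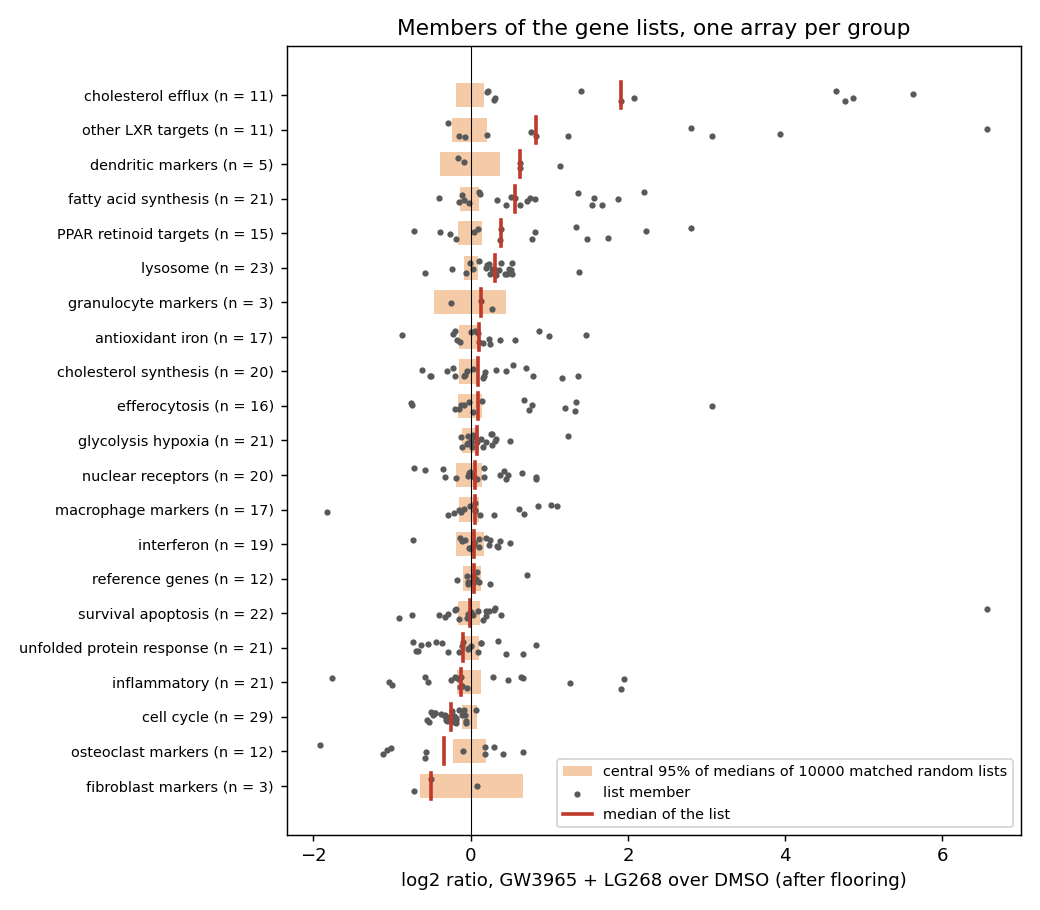
Log2 ratio of the ligand array over the DMSO array (x axis, after flooring) for the measured members of each gene list (grey points), with the list median (red line) and the central 95% of the medians of 10000 random lists matched on signal (orange bar). The medians of cholesterol efflux, other LXR targets, fatty acid synthesis, PPAR and retinoid targets and lysosome lie to the right of their bars, that of the dendritic markers does so on 5 genes, and those of cell cycle and osteoclast markers lie to the left.

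Several of the largest differences lay outside these lists. Scd3, a stearoyl-CoA desaturase, was 17.8-fold higher (312 and 5542), and detection of transcripts of other desaturases by its probe set was not excluded. Igf1, insulin-like growth factor 1, was 9.80-fold higher, with a second probe set at 2.60 on the log2 scale, and the ERK phosphatase Dusp6 was 8.15-fold higher (1317 and 10736). The organic anion transporter Abcc3 was 6.88-fold higher, Tmem86a, a lysoplasmalogenase, 6.68-fold, Tifab 6.60-fold, AB124611 6.31-fold, the proteoglycan Sdc3 5.88-fold and the annexin Anxa3 4.96-fold higher. Among genes at the floor with DMSO, the T cell costimulatory receptor Cd28 was at least 5.97-fold and the lysosomal channel Mcoln2 at least 4.77-fold higher.

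On the lower side, genes were no more numerous at 2-fold and 4-fold than in the simulation without change. Among genes whose brighter signal exceeded 2178 they were, with 21 at least 2-fold lower against 4. Of the simulated genes at 2-fold, 92 higher and 88 lower, only 4 and 4 exceeded that signal. Single ratios at weak signals may therefore be noise in either direction. Cx3cr1, Acp5 and Cxcl2 were joined by Klf4, a Krüppel-like transcription factor (3.79-fold lower, 5055 and 1333, second probe set -1.12). Cadps was 4.18-fold lower (1749 and 418), Rbfox1 4.13-fold (1640 and 397), Tmem26 3.54-fold and Hr 3.07-fold lower, each from 1 probe set above the floor. Ptchd1 was 3.99-fold and Sema5a 3.50-fold lower, but other probe sets of these genes gave only -0.22 and -0.60 on the log2 scale. The serotonin receptor Htr1b was at least 11.8-fold lower (3263 with DMSO and below the floor with the ligands). Rgs16, Ambp, Nkain1 and Slfn10-ps were at least 4.13-fold, 3.83-fold, 3.76-fold and 2.95-fold lower, all to below the floor.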

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

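The choice of floor moved the counts of genes most. With the floor at the 25th percentile 1348 genes were at least 2-fold higher and 1335 lower, and with log2(signal + 32) and no floor 1694 and 1685, a higher share of 50.2% and 50.1% in place of 68.3%. With the floor at the 75th percentile the counts were 71 and 13. With both signals above the floor 57 genes were lower. At 1.5-fold the counts were 705 and 528, and at 3-fold 55 and 14. Quantile normalization, centring, averaging probe sets and leaving out _s_at and _x_at probe sets kept both counts within 1.5 times, and rescaling to 1 trimmed mean moved nothing, since the arrays already shared it. The cholesterol efflux median was 1.41 with the lower floor, 0.86 without a floor, 2.19 with averaged probe sets and 1.66 with both signals above the floor, above all random lists each time. Fatty acid synthesis was 0.66 and sterol synthesis 0.022 with averaged probe sets. PPAR and retinoid targets were 0.23 without a floor (99.55th percentile), 0.48 with averaged probe sets and 0.58 without _s_at and _x_at probe sets. Efferocytosis was -0.025 with the lower floor, the higher floor and no floor (47.1st, 49.2nd and 50.9th percentiles), and 0.00203 with both signals above the floor (61.8th percentile). The osteoclast median was -0.10 with the higher floor and -0.57 with both signals above the floor. The dendritic median was 0.20 with the lower floor, 0.37 without a floor and reversed to -0.088 with both signals above the floor, where its members at the floor drop out. Nuclear receptors were 0.17 with the higher floor and fibroblast markers -0.16 without a floor. After quantile normalization the lysosomal median was 0.25 and the unfolded protein response -0.16. With averaged probe sets glycolysis was 0.16 and antioxidant genes 0.21, and the latter 0.23 without _s_at and _x_at probe sets. Where no reason is given, the cause was not tested. Without matching on signal, the fibroblast list moved to the 1.63rd percentile, and no other list changed its side of the central 95%. Of the 55 named genes at least 2-fold apart, 7 lost 2-fold with the higher floor (Tgm2, Acp5, Arg2, Mertk, Dhrs3, Ctsk and Htr1b) and 16 more then had no value, and Ptchd1 and Sema5a lost it with averaged probe sets. Named ratios moved by more than the probe set SD in 56 of the cases and did not in 570. The 570 include 74 cases each from rescaling and from centring, which could not move a ratio that far. With the higher floor 22 moved and 27 did not, and with averaged probe sets 18 moved and 56 did not. No named gene at least 2-fold apart changed sign under these alternatives, and of all 271 genes at least 2-fold apart 1 did, without _s_at and _x_at probe sets. This says little, since another floor, the added 32, rescaling or requiring both signals above the floor cannot reverse a sign. Averaging or leaving out probe sets could, but the genes named for the largest and smallest ratios were chosen with probe sets in 1 direction. With the hybridisation spike-ins as the reference, ratios of genes above the floor on both arrays would be about 0.27 lower on the log2 scale. The order of those genes would stay. The counts at 2-fold would change, and small positive medians, such as 0.05 for macrophage markers, would become negative. These spike-in probe sets ranged from 0.02 to 0.63, and the poly-A spike-ins, with a median of 0.03, would give almost no shift. The counts were not repeated with either reference. No paired analysis was possible because each group had 1 array, and no replicate could be left out.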

Other observations

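Gene lists were drawn up here from genes whose values had not been looked at, and their predictions were written before the list medians were computed. The ratios of single genes, such as that of Fos, had been computed by then. The tests of signal level and of the number of cultures were chosen after the result was seen. Amino acid response genes formed the clearest group not described above. Of 30 measured genes known as ATF4-regulated, most of them for amino acid synthesis, amino acid transport or tRNA charging and some for stress regulators such as Nupr1 and Atf5, 26 had lower signals with the ligands by the brightest probe set of each. In 5 of these 26 another probe set was higher, up to 0.86 for Slc7a1, 0.29 for Phgdh, 0.18 for Gpt2, 0.11 for Aldh18a1 and 0.06 for Shmt2. The median log2 ratio was -0.32, below all 10000 random lists matched on signal. Aldh18a1, which starts proline synthesis, was 1.77-fold lower, but its 5 probe sets had log2 ratios from -0.82 to 0.11. The glycine transporter Slc6a9 was 1.75-fold lower (-0.81 and -0.12 in its 2 probe sets), the glutamyl-prolyl tRNA synthetase Eprs was lower in all 4 probe sets (-0.58 to -0.16), and the mitochondrial folate enzyme Mthfd2 was 1.45-fold lower (-0.66 and -0.53). The 4 members that went the other way were the seryl tRNA synthetase Sars, Ddit4, Slc38a2 and Stc2, at log2 ratios of 0.35, 0.22, 0.20 and 0.01. The 3 probe sets of Slc38a2 ranged from -0.11 to 0.59. DNA replication genes were lower in 27 of 27 measured members by the brightest probe set of each, with Chek1 1.56-fold (-0.64 and -0.56 in 2 probe sets) and Gins3 1.54-fold lower (-0.63 and -0.37). In 5 of the 27 another probe set was higher, up to 0.60 for Uhrf1, 0.55 for Gins1, 0.37 for Mcm10, 0.32 for Cdc45 and 0.12 for Orc1.

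The list that prompted the first group held Trib3, Chac1 and Asns, picked because they were lower with the ligands, while Atf3 and Ppp1r15a in it were not. A hypothesis is that the ligand culture had a lower amino acid response in general, and the separate list, at -0.32, is consistent with it. Over the alternative settings its median stayed between -0.34 and -0.28. A difference in nutrient state or density between the 2 cultures could give the same values, and with 1 control array this cannot be told apart from an effect of the ligands.

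The small but uniform shift of cell cycle genes, with a median log2 ratio of -0.26, was followed up in the same way. The DNA replication list had a median of -0.30, below all random lists. The mitosis list had -0.24, with 23 of 28 members lower by the brightest probe set. In 7 of the 23 another probe set was higher, up to 0.35 for Kif2c. Both parts of the program were thus lower on these 2 arrays. These genes belong to the same program as the first list and were read from the same arrays. The 2 lists therefore extend the pattern to more genes and are not independent support for it. A bias with signal level is argued against by these 2 separate lists, whose medians both lay at or below the 0.01st percentile among lists matched on signal level. These are the same percentiles read again, after they had been seen, and not further evidence. What stays open is a difference between 2 single cultures unrelated to the ligands, because there was 1 control array; a lower growth rate with the ligands would be the biological reading and is untested.

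The osteoclast markers gave a different outcome. Their median lay at the 0.15th percentile of matched random lists, and at the 15th with the higher floor. A list of other osteoclast genes had a median of -0.052, with 6 of 12 lower, at the 42.3rd percentile of random lists. Over the alternative settings it ranged from -0.14 to 0.049, so its direction was not fixed. The main value lies inside the central 95% of random lists and decides neither for nor against a wider lower osteoclast program. Its lowest member was Slc9b2, at least 1.66-fold lower and below the floor with the ligands.

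Because Klf4 was lower, and Fos as well with a log2 ratio of -1.17, 20 other measured immediate early genes were tested for a common direction. Their median was 0.10, with 12 higher and 8 lower, at the 93.05th percentile of random lists. This lies inside the central 95%, from -0.17 to 0.14. A wider lower immediate early response predicted a median below that range. The prediction without it, a median at or above that of the random lists (-0.02), was met. Over the alternative settings the median stayed between 0.08 and 0.12. These values argue against a lower response shared by these genes on these 2 arrays, although 8 of them were lower. Btg2 was 2.15-fold higher and Klf6 had log2 ratios of -1.10 to -0.57 in 4 probe sets. Of 3052 measured probe sets with no gene symbol, 43 were at least 2-fold higher and 57 at least 2-fold lower with the ligands.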
